A study of Macaca mulatta with 44 samples.

How the data were processed

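Small RNA from the duodenum of 12 rhesus macaques was profiled with TaqMan microRNA assays, which read each miRNA by stem-loop reverse transcription, preamplification and real-time PCR. The 44 samples fell into 10 groups by their titles. Every animal gave 1 sample titled preinfection (Pre), and the titles do not say whether it preceded treatment. Animals of the arm called THC-only (uninfected, 3 animals), VEH-SIV (infected, vehicle, 4 animals) and THC-SIV (infected, Δ9-tetrahydrocannabinol, 4 animals) were sampled again on days 14, 30 and 60. 1 THC-SIV animal gave no day 30 sample here, and 1 animal gave a Pre sample alone. Per the series text, samples up to day 30 were pinch biopsies and day 60 was necropsy. The series text gives vehicle to the arm it names THC/SIV and Δ9-THC to the one it names VEH/SIV, so the treatment of the infected arms rests on the sample titles here. The sources name 2 formats of the assay panel and different RNA inputs, and the format was not settled here.

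The authors deposited threshold cycles (Ct) without normalization, per the file headers, with 1 value per assay and sample. A lower Ct is more template, and 1 cycle was read as 1 log2 unit, which assumes doubling in each cycle. The deposited Ct table held 762 assays, of which 754 were miRNA assays in pools A and B (377 each), 6 were endogenous controls (RNU44, RNU48 and U6 in both pools) and 2 were a plant miR159a. Ct 40 stood for not detected and filled 34.5% of the cells, and the lowest Ct was 1.43. The authors also deposited ΔCt on the log2 scale, which is the Ct minus 1 control value per sample, with 0 written where the Ct was 40. In 42 samples Ct minus ΔCt was constant over the assays, and the ΔCt columns of the THC-only day 14 samples of HM74 and HE44 held each other's values (SD 0 over 501 and 507 assays once exchanged). The labels of the Ct table were kept. RNU44 in pool B minus pool A runs against them: it was −0.36 in the sample labelled HM74, which had 1.50 and 1.82 on days 30 and 60, and 0.90 in the one labelled HE44, which had 0.09 and −0.19. The sample labelled HE44 also correlated more with the others of HM74 (mean r 0.28) than of HE44 (0.01), while the sample labelled HM74 had 0.02 with HM74 and −0.11 with HE44. The labels were left open, and exchanging them was run as an alternative. They do not enter the fits without animal or cohort. The authors' control value lay 0.20 to 0.26 above the mean of the 6 control readings in all 12 Pre samples and in 0 of the 32 later samples, where its median distance was 0. Among the 42 samples with a constant difference it was over 0.3 away in 2, both VEH-SIV day 30 (FE07 and HH45). Once the 2 columns were exchanged, the control value of THC-only day 14 HM74 was 17.171 against a mean of 17.742, also over 0.3 away. Another deposited table gave the authors' ratios (fold changes) and p-values of 12 comparisons, with no test named in its header. Of its 525 assay lines with values, 269 matched a ratio recomputed from the deposited ΔCt within 0.1 log2, and 248 of these belonged to the assay 1 line above, 21 elsewhere and 0 to their own line. That table was therefore used as counts of p-values, by direction where stated, and not for single miRNAs.

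From the deposited Ct, −ΔCt was computed as the mean Ct of the 6 control readings minus the assay's Ct, so that higher is more. A Ct under 35 was detected and other values were left missing. An assay was tested if detected in at least 33 of the 44 samples and in at least 2 samples of each group compared, which gave 403 assays, 251 of them detected in every sample. Each comparison was made with limma 3.58.1 (lmFit and eBayes, R 4.3.3) in 1 fit of all 44 samples with 10 groups, with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05. THC-SIV and VEH-SIV were also compared on each animal's mean over its later samples, 4 animals against 4. The limma step was tested with simulated changes of 1 log2 in about 100 assays and of 2 log2 in about 100 others of the same fit. Of 403 assays 203 stayed unchanged, so the shares recovered may not hold where fewer assays change. Noise was drawn for each assay on its own and changes went both ways, so they may not hold where whole samples shift either. For THC-SIV-60 against Pre the step recovered 38% of changes of 1 log2 and 57% of changes of 2. For THC-SIV-60 against VEH-SIV-60 it recovered 24% and 56%. For THC-SIV-60 against THC-only-60, with 400 assays, it recovered 16.3% and 50%, and for THC-only-60 against Pre, with 400 assays, 21.2% and 49%. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

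A list value was the mean over the list's tested members of −ΔCt minus the member's mean over all samples, and group means were compared by an exact two-sided permutation test with Benjamini-Hochberg adjustment over 13 lists. The smallest exact p was 0.000549 for 4 samples against 12, 0.0022 for 3 against 12, 0.0286 for 4 against 4 or 3, and 0.1 for 3 against 3. Because the control RNAs and the miRNAs as a whole moved apart between Pre and later groups, list values are reported relative to the mean of all tested assays, and single miRNAs also under global mean normalization (the mean Ct of the 251 assays replacing the controls). The lists were markers of intestinal epithelium (11 tested members), smooth muscle (5), fibroblasts with an imprinted stromal cluster (30), endothelium (2), leukocytes (9), myeloid cells (3), erythrocytes (4) and neurons (8), miRNAs responsive to inflammation (8), miRNAs reported to target lentiviruses (9), the miR-17 family (13), the let-7 family (8) and 6 miRNAs recalled as anti-inflammatory from the study's own report. The last list was chosen by the study on these samples and is not independent evidence. miR-145 is in that list and in the smooth muscle list, miR-31 in the epithelial and inflammation lists, miR-146a, miR-146b and miR-155 in the leukocyte and inflammation lists, miR-147b in the myeloid and inflammation lists, miR-223 in the myeloid and lentivirus lists, miR-150 in the leukocyte and lentivirus lists, miR-382 in the fibroblast and lentivirus lists, and miR-9 in the neuronal and inflammation lists.

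The comparisons, tests, lists, filters and alternatives were chosen before the data were examined. The miRNAs named were the 12 largest changes past the threshold in each direction or, where fewer than 10 passed, the 10 smallest p, with all 6 members of the study's list in infected comparisons and up to 4 examples of a list. Samples of 1 animal share a name in the titles and were treated as paired in an alternative fit with the animal as a block (replicate block). The median of the controls, the cohort as a factor, the fits without samples standing apart, and the exchanged labels were alternatives added later, with values in view. Deviations from group means of the same animal had a median r of 0.20 over 63 pairs, against 0.17 for other animals of the same cohort and −0.18 across cohorts. The 2 cohorts of 6 animals each were found in the data, from the sign of RNU44 in pool B minus pool A in Pre, and are not groups of the study; they divide the infected arms evenly, 2 animals each. Alternatives changed the normalization (global mean, the authors' deposited ΔCt, RNU44 and RNU48, U6, the median of the controls), the Ct limit (32 or 40), the treatment of missing values, the detection filter, the block, the samples in the fit and each sample in turn. Precision is limited by the number of animals, since Ct tables hold no counts. Fisher's exact test compared detection of assays under the filter.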

Results

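The study asked how duodenal miRNAs change during infection of rhesus macaques with simian immunodeficiency virus (SIVmac251), given at 100 TCID50, and whether chronic Δ9-THC, begun 4 weeks before infection, alters that change. It measured 754 miRNA assays in 44 samples of 12 animals. Pre held 12 samples, THC-only 3 on each of days 14, 30 and 60, VEH-SIV 4 on each day, and THC-SIV 4 on day 14, 3 on day 30 and 4 on day 60. Pre samples had 378 to 421 detected miRNA assays and the 32 later samples 487 to 553, with no overlap. The gap was in pool A (225 to 262 against 274 to 307) and in pool B (147 to 174 against 208 to 261). RNU44, a small nucleolar RNA used as a control, had a mean Ct of 22.9 ± 0.254 (SD, n = 12) in Pre and of 24.1 ± 0.546 (SD, n = 4) in THC-SIV-60 (exact permutation p = 0.000549). There RNU48 differed by 0.29 and U6 by −0.20 cycles (exact permutation p = 0.203 and 0.488), while the mean Ct of the miRNAs was lower by 1.00 (exact permutation p = 0.000549). The mean control Ct lay closer to the mean of all miRNAs in later groups, by 1.43 cycles in THC-SIV-60 (exact permutation p = 0.000549, adjusted p = 0.000824) and by 0.32 in VEH-SIV-14 (exact permutation p = 0.107, adjusted p = 0.138). Which part moved differed by group. In VEH-SIV-30 the mean control Ct was higher than in Pre by 1.03 and the mean miRNA Ct by 0.04 (exact permutation p = 0.0033 and 0.751). In THC-only-14 these were 0.84 and 0.25 (exact permutation p = 0.0022 and 0.165). In VEH-SIV-60 they were 0.20 and −0.56 (exact permutation p = 0.319 and 0.00165).

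**Figure D1:**
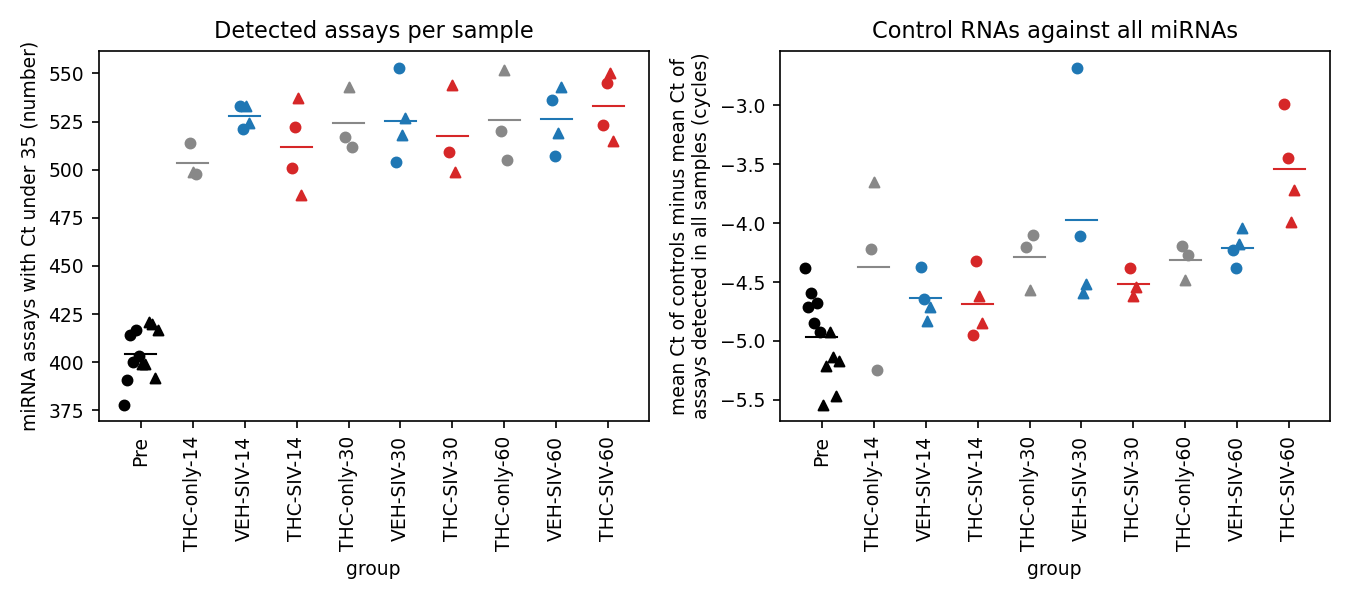
Number of miRNA assays with a Ct under 35 (left) and mean control Ct minus mean miRNA Ct in cycles (right) in each sample by group, with circles for cohort 1, triangles for cohort 2 and lines for group means. The Pre samples hold at most 421 detected assays and the later samples at least 487.

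Against Pre, the median of all tested assays was higher by 0.32 log2 in VEH-SIV-14, 1.00 in VEH-SIV-30, 0.68 in VEH-SIV-60, 0.30 in THC-SIV-14, 0.48 in THC-SIV-30, 1.37 in THC-SIV-60, 0.58 in THC-only-14, 0.62 in THC-only-30 and 0.64 in THC-only-60. It was higher by 0.70 in THC-SIV-60 than in VEH-SIV-60 and by 0.75 than in THC-only-60. Of 421 calls against Pre 419 were higher (99.5%), and under global mean normalization 80 of 146 were (54.8%). Changes of single miRNAs below are therefore given relative to the control RNAs and then under global mean normalization, and list differences relative to all assays. On the control scale 35 of 195 list differences passed the threshold, all higher, and relative to all assays 9 did, 5 higher and 4 lower.

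The VEH-SIV groups were compared with Pre to ask what infection does without THC. Day 60 was necropsy and Pre biopsy, so infection and sampling are not separated on that day. On day 60 the smooth muscle miRNAs rose together: miR-143 by 2.56 ± 0.29 log2 (standard error, 4 against 12 samples, adjusted p = 9.19e-08, 1.81 under global mean) and miR-1, a miRNA of striated and smooth muscle, by 2.60 ± 0.50 (adjusted p = 0.000248, 1.84 under global mean). All 5 members passed the threshold over all assays and when adjusted over the list alone, and under global mean 4 did (5 over the list alone). The list stood 1.45 log2 above Pre relative to all assays in 4 of 4 samples (exact permutation p = 0.0011, adjusted p = 0.0143; 1.60 in cohort 1 and 1.30 in cohort 2). miR-99a, miR-125b and miR-218 were also higher on day 60, by 2.43 ± 0.43, 2.20 ± 0.43 and 2.37 ± 0.37 (adjusted p = 0.00013, 0.0003 and 2.03e-05). Under global mean these were 1.68, 1.44 and 1.61. In uninfected THC-only-60 miR-218 was higher than Pre as well, by 1.72 ± 0.41 (adjusted p = 0.00736). miR-190b was higher than Pre in 4 of 4 samples on every day, by 3.21 ± 0.69 on day 14 (adjusted p = 0.0191, 2.89 under global mean), 3.24 ± 0.69 on day 30 (adjusted p = 0.0021) and 2.56 ± 0.69 on day 60 (adjusted p = 0.00679). Under global mean normalization its adjusted p was 0.0365 on day 14, 0.174 on day 30 and 0.0966 on day 60. Epithelial, fibroblast and leukocyte lists differed from Pre on day 60 by −0.20, 0.35 and −0.19 relative to all assays, with adjusted p of 0.693, 0.207 and 0.693 from the exact permutation test. On the control scale they were higher by 0.52, 1.07 and 0.53 (adjusted p = 0.0125, 0.00429 and 0.0838).

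In the study's anti-inflammatory list, chosen by the study on these samples, 4 of 6 members rose in VEH-SIV-60 (4 also when adjusted over the list alone; under global mean 0, and 1 over the list alone), among them miR-145, abundant in smooth muscle, by 1.70 ± 0.32 (adjusted p = 0.000248, 0.94 under global mean) and miR-149 by 1.06 ± 0.29 (adjusted p = 0.0078, 0.30 under global mean). On day 30 3 of 6 rose (4 over the list alone; under global mean 0, and 1 lower over the list alone), of which miR-149 (0.78 ± 0.29, adjusted p = 0.0402) and miR-24 (0.92 ± 0.29, adjusted p = 0.0195) turned to −0.21 and −0.07 under global mean. On day 14 none of the 6 passed over all assays in limma, where 34 of 403 assays had an unadjusted p under 0.05. There miR-145 was the 1 member past the threshold over the list alone (−1.04 ± 0.32), and it fell by 1.37 under global mean (adjusted p = 0.0365). Relative to all assays the list differed from Pre by −0.43, −0.19 and 0.32 on days 14, 30 and 60 (adjusted p of the exact permutation test 0.316, 0.564 and 0.479). On the control scale it was higher by 0.84 on day 30 and 1.04 on day 60 (adjusted p = 0.0407 and 0.00714).

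The counts in VEH-SIV were 1 assay higher on day 14, 120 higher on day 30 and 79 higher on day 60. Under global mean they were 2 (1 higher, 1 lower), 0 (29 with an unadjusted p under 0.05) and 35 (24 higher, 11 lower). Within cohorts (2 against 6 samples) day 60 gave 3 assays in cohort 1 and 162 in cohort 2, and 32 and 47 under global mean. On day 30 RNU48 in pool B had a Ct of 18.6 in FE07 and 18.22 in HH45, the highest of all samples, as was RNU44 in pool A of FE07 at 27.73. The count of that day was 1 with the authors' deposited normalized table. Among the day 30 calls were miR-543 and miR-381, both of the imprinted stromal cluster (2.13 ± 0.34, adjusted p = 0.00019, 1.19 under global mean; 8.91 ± 2.06, adjusted p = 0.004, detected in 2 of 4 samples). The paired fit with the animal as a block gave 47 assays on day 30 and 51 on day 60. In it miR-149 and miR-24 were not past the threshold on day 30 (adjusted p = 0.252 and 0.0671), nor miR-149 on day 60 (adjusted p = 0.129). Without VEH-SIV-30 FE07, which had the highest mean control Ct of the 4, the refit called 5 assays on day 30. Without HN54 or HT49 it called 52 (51 higher, 1 lower) or 46 on day 60, and without FE07 or HH45 0 on day 14.

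The THC-SIV groups were compared with Pre to follow infection under THC. On day 60 smooth muscle miRNAs rose (miR-143 by 3.38 ± 0.29, adjusted p = 5.85e-11, and miR-1 by 3.57 ± 0.50, adjusted p = 3.86e-07; 1.95 and 2.14 under global mean), and all 5 members passed, over all assays and over the list alone. Among other miRNAs past the threshold, miR-10b rose by 3.67 ± 0.50 (adjusted p = 2.44e-07), miR-99a by 3.66 ± 0.43 (adjusted p = 3.45e-08), miR-224 by 3.59 ± 0.43 (adjusted p = 3.67e-08), let-7c by 3.51 ± 0.49 (adjusted p = 3.98e-07) and miR-218 by 3.43 ± 0.37 (adjusted p = 6.08e-09). Under global mean these were 2.24, 2.24, 2.16, 2.09 and 2.00. The epithelial miRNAs went the other way relative to all assays. Their list stood at −1.54 in 4 of 4 samples (exact permutation p = 0.00165, adjusted p = 0.00714), with −2.03 in cohort 1 and −1.05 in cohort 2. Leaving out GP68 gave −1.02 (exact permutation p = 0.00659). Under global mean 10 of 11 members fell (11 when adjusted over the list alone), including miR-375 by −1.92 ± 0.39 (adjusted p = 0.000247), miR-200b by −1.69 ± 0.27 (adjusted p = 1.35e-05) and miR-192 by −1.68 ± 0.34 (adjusted p = 0.000247). On the control scale none of the 11 passed in limma and the list difference was −0.15 (exact permutation p = 0.605). Without GP68 that value turned to 0.31, past the threshold in the opposite direction (exact permutation p = 0.0396, adjusted p = 0.0468). miR-194*, the passenger strand of an epithelial miRNA, and miR-182 fell on both scales (−0.93 ± 0.28, adjusted p = 0.00729, −2.36 under global mean; −2.33 ± 0.86, adjusted p = 0.0261, −3.75 under global mean).

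Relative to all assays, 5 of the 13 lists differed from Pre in THC-SIV-60, the epithelial list among them. The smooth muscle list was higher by 1.71 and the fibroblast list by 0.89 (exact permutation p = 0.000549 and adjusted p = 0.00357 each). The study's list was higher by 0.81 (exact permutation p = 0.0022, adjusted p = 0.00714). The list responsive to inflammation was lower, at −0.80 (exact permutation p = 0.0181, adjusted p = 0.0471). On the control scale it was higher instead, by 0.59 (exact permutation p = 0.0484, adjusted p = 0.0524), with 2 members past the threshold in limma, both higher, and under global mean 3, all lower. On that control scale 11 of the 13 lists passed, all higher. In the fibroblast list 21 of 30 members rose (22 over the list alone), and under global mean 12 did (12 over the list alone). The remaining differences were 1.13 for endothelium (adjusted p = 0.125), −0.35 for leukocytes (adjusted p = 0.337), and −0.18 for myeloid cells (adjusted p = 0.519). They were 0.54 for erythrocytes (adjusted p = 0.514), −0.11 for neurons (adjusted p = 0.636), and 0.39 for lentivirus-targeting miRNAs (adjusted p = 0.125). The erythrocyte mean hides a split, with 2.71 in FT59 and 2.15 in GP68 against −1.35 in HN56 and −1.40 in HV47. Endothelium stood at 1.81 and 2.00 in FT59 and GP68 against 0.03 and 0.57 in HN56 and HV47. The families stood at −0.54 for the miR-17 family (adjusted p = 0.0602) and 0.47 for the let-7 family (adjusted p = 0.0548). In the study's list 5 of 6 members rose (6 over the list alone), with miR-145 at 2.88 ± 0.32 (adjusted p = 1.17e-08), miR-99b at 2.28 ± 0.37 (adjusted p = 4.39e-06), and miR-10a at 2.25 ± 0.46 (adjusted p = 0.000103). The others were miR-149 at 2.17 ± 0.29 (adjusted p = 2.27e-07), miR-24 at 2.04 ± 0.29 (adjusted p = 6.76e-07) and miR-187 at 1.56 ± 0.68 (adjusted p = 0.0599). Under global mean 3 of them did (5 over the list alone), miR-145 at 1.45, miR-99b at 0.86 and miR-149 at 0.74.

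In THC-SIV miR-190b was above Pre in 4 of 4 samples on day 14 (2.67 ± 0.69, adjusted p = 0.0634) and in 3 of 3 on day 30 (2.90 ± 0.78, adjusted p = 0.0975). On day 60 it was above Pre in 4 of 4 (2.92 ± 0.69, adjusted p = 0.000738). Under global mean its values were 2.39, 2.45 and 1.49 (adjusted p = 0.129, 0.222 and 0.104). On day 30 miR-223, a granulocyte miRNA, and miR-21, which inflammation induces, were at 1.19 ± 0.35 and 1.17 ± 0.35 (adjusted p = 0.102 each). The let-7 list stood at −0.32 relative to all assays on day 14 in 4 of 4 samples (exact permutation p = 0.0011, adjusted p = 0.0143), against 0.11 on the control scale and −0.16 under global mean (exact permutation p = 0.116, adjusted p = 0.521). The 1 assay past the threshold on day 14, miR-575 (10.34 ± 1.67, adjusted p = 0.000449), was detected in 3 of 4 samples. On day 30 limma gave 0 assays, with 50 at an unadjusted p under 0.05. Within cohort 2 (2 against 6 samples) day 30 gave 47 assays, all higher, and 0 under global mean. Day 14 gave 13 in cohort 2 (2 under global mean) and 0 in cohort 1. Day 60 gave 177 assays, 175 higher and 2 lower, and 98 under global mean, 47 higher and 51 lower. Without FT59 and GP68 it gave 91. The paired fit gave 0 on day 14. Leaving out Pre GH61, GP68 or HV47 gave 2, 3 and 2 on day 14, and leaving out HN56 or HV47 gave 1 each on day 30.

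**Figure D2:**
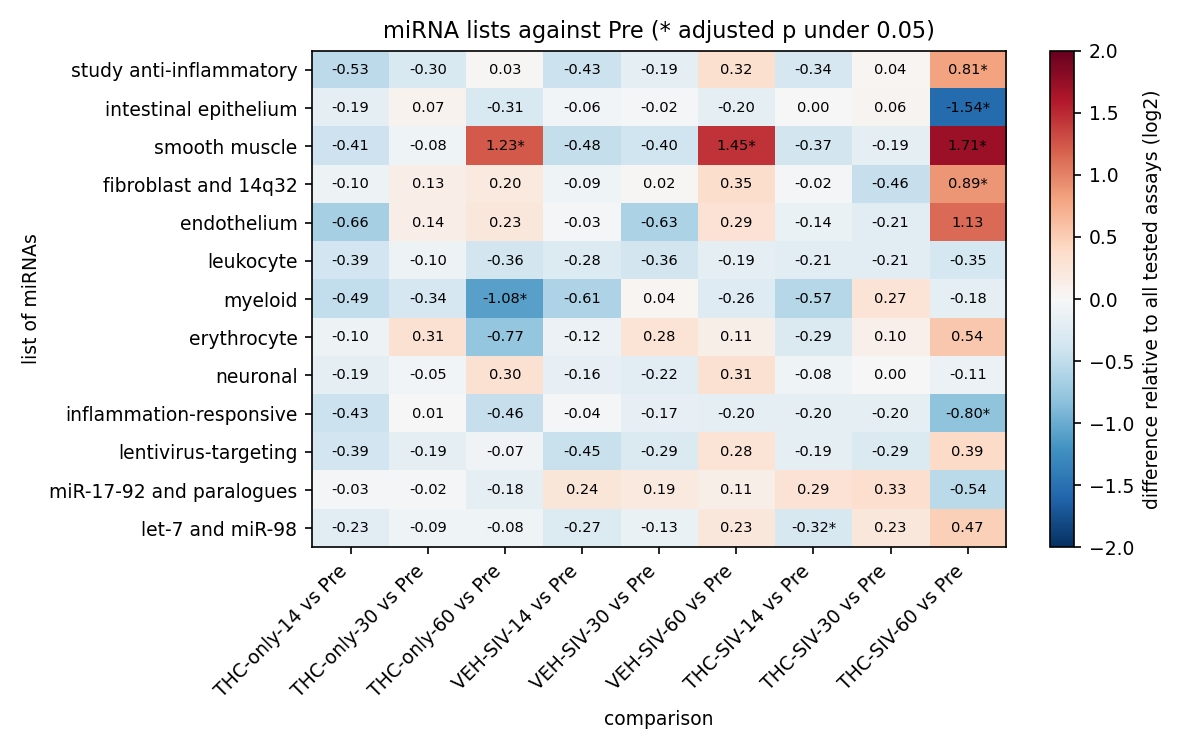
Difference of each list from Pre in log2 relative to all tested assays, for the 9 later groups, with colour and number giving the difference and a star an adjusted p under 0.05 by the exact permutation test. The smooth muscle list is higher by 1.23, 1.45 and 1.71 on day 60 in THC-only, VEH-SIV and THC-SIV, and the epithelial list is lower by over 1 log2 in THC-SIV-60 alone.

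The THC-only groups were compared with Pre to see THC without infection. No later group was both uninfected and without THC, so against Pre neither THC nor infection can be told from time. Day 60 also differs from Pre in sampling, necropsy against biopsy. On day 60 smooth muscle miRNAs rose here too: miR-143 by 2.34 ± 0.33 (3 against 12 samples, adjusted p = 9.65e-06, 1.69 under global mean), miR-1 by 2.29 ± 0.55 (adjusted p = 0.00749, 1.64 under global mean) and miR-133b, a muscle miRNA, by 1.91 ± 0.40 (adjusted p = 0.00249, 1.26 under global mean). All 5 members passed (5 over the list alone), and 3 did under global mean (5 over the list alone), without miR-133a (1.61, 0.96 under global mean, adjusted p = 0.146 there) and miR-145 (1.52, 0.87 under global mean, adjusted p = 0.221 there). The list stood 1.23 above Pre relative to all assays (exact permutation p = 0.00659, adjusted p = 0.0429) in 3 of 3 samples. The myeloid list, of which 3 members were tested, was lower by the same test (−1.08, exact permutation p = 0.0022, adjusted p = 0.0286), while on the control scale it stood at −0.37 (exact permutation p = 0.325). The study's list stood at 0.03 (adjusted p = 0.901) and the epithelial list at −0.31 (adjusted p = 0.469). miR-190b, looked up here after its values in the infected groups were seen, was at 0.22, 0.04 and 0.65 log2 on days 14, 30 and 60 (standard error 0.78 each, adjusted p = 0.902, 0.972 and 0.679). On day 30 miR-96, of the miR-183 cluster, rose by 1.57 ± 0.35 (adjusted p = 0.0177, 0.89 under global mean) and miR-9* by 2.54 ± 0.57 (adjusted p = 0.0177, 1.87 under global mean), and on day 14 miR-130b* rose by 1.77 ± 0.46 (adjusted p = 0.0471, 1.25 under global mean).

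The counts in THC-only were 4, 11 and 28 on days 14, 30 and 60, all higher, and 0, 0 and 10 (7 higher, 3 lower) under global mean (limma, 20, 16 and 61 with an unadjusted p under 0.05). The paired fit gave 0, 0 and 2, the latter miR-143 and miR-145*. Leaving out GH61, HM74 or HE44 gave 2, 0 and 9 on day 14, leaving out GH61 or HE44 gave 7 and 6 on day 30, and leaving out GH61, HM74 or HE44 gave 12, 8 and 18 on day 60.

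THC-SIV was compared with VEH-SIV on each day to ask what THC adds during infection. On day 60 all 6 members of the study's list were higher in THC-SIV, from 0.84 ± 0.36 for miR-24 to 1.40 ± 0.56 for miR-10a, with miR-149 at 1.11 ± 0.36, miR-145 at 1.18 ± 0.40, miR-99b at 1.10 ± 0.45 and miR-187 at 1.31 ± 0.83. None passed over all assays (adjusted p from 0.113 to 0.369), and 5 did when adjusted over the list alone, a list that is not independent evidence. The median of all assays was itself higher by 0.70, and under global mean the 6 values ran from 0.17 for miR-24 to 0.73 for miR-10a, with 0 past the threshold over all assays or over the list alone. Relative to all assays the list differed by 0.49 (exact permutation p = 0.143, adjusted p = 0.433). Among other miRNAs, miR-214, a stromal miRNA, was at 1.75 ± 0.48, miR-126, the endothelial marker, at 1.47 ± 0.42, and miR-127, of the imprinted cluster, at 1.64 ± 0.52. Each had an adjusted p of 0.113, and under global mean they were 1.08, 0.81 and 0.97.

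Epithelial miRNAs were lower in THC-SIV-60 than in VEH-SIV-60. All 11 members lay below 0 on either scale, none past the threshold relative to the control RNAs. Under global mean 4 fell over all assays and 11 over the list alone: miR-31 at −1.35 ± 0.32, miR-194 at −1.42 ± 0.35 and miR-200b at −1.33 ± 0.33 (adjusted p = 0.0315 each), and miR-141 at −1.69 ± 0.45 (adjusted p = 0.0486). The passenger strand miR-200b* fell on that scale as well (−1.70 ± 0.37, adjusted p = 0.0179). As a list they stood at −1.33 relative to all assays (exact permutation p = 0.0857, adjusted p = 0.433). It stood at −2.0 in cohort 1 and −0.67 in cohort 2. Leaving out GP68 gave −0.82 (exact permutation p = 0.171) and leaving out HN56 gave −1.71 (exact permutation p = 0.0286). FT59 and GP68, the lowest epithelial samples, also had the highest mean control Ct minus mean miRNA Ct of day 60 (−2.99 and −3.45), a measure that differed by 0.67 between the groups (exact permutation p = 0.0286, adjusted p = 0.257). Among other lists the differences were 0.54 for fibroblasts (exact permutation p = 0.0571), 0.84 for endothelium (exact permutation p = 0.2), and −0.65 for the miR-17 family (exact permutation p = 0.114). They were −0.59 for the list responsive to inflammation (exact permutation p = 0.2), 0.27 for smooth muscle (exact permutation p = 0.571), −0.15 for leukocytes (exact permutation p = 0.857) and −0.42 for neurons (exact permutation p = 0.343). None of these passed adjustment. Erythrocyte values were 2.71 and 2.15 in FT59 and GP68 and −1.35 and −1.40 in HN56 and HV47, against −0.87 to 1.25 in VEH-SIV-60.

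limma called 0 assays on each of days 14, 30 and 60, with 17, 26 and 81 at an unadjusted p under 0.05, and 5 on day 60 under global mean, all lower. Each animal's mean over its later samples gave 0 as well, with 5 at an unadjusted p under 0.05, where the study's 6 miRNAs ran from 0.20 ± 0.27 for miR-149 to 0.58 ± 0.37 for miR-145 (adjusted p = 0.98 each). On day 14 the 6 ran from −0.09 ± 0.45 for miR-99b to 0.61 ± 0.40 for miR-145, and on day 30 from −0.79 ± 0.39 for miR-149 to 0.21 ± 0.90 for miR-187. On day 30 the fibroblast list was at −0.48 (exact permutation p = 0.0571, adjusted p = 0.743), with miR-543 at −1.35 ± 0.44 and miR-381 at −9.35 ± 2.43 (adjusted p = 0.656 and 0.222). Without HN56 day 60 gave 45 assays and without HV47 12. Within cohort 1 (2 against 2 samples) 56 assays passed (54 higher, 2 lower), and 43 under global mean (17 higher, 26 lower). It was 0 within cohort 2 in limma, with 29 at an unadjusted p under 0.05. With the cohort as a factor day 60 gave 0, and 27 once the labels of HM74 and HE44 in THC-only-14 were exchanged.

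**Figure D3:**
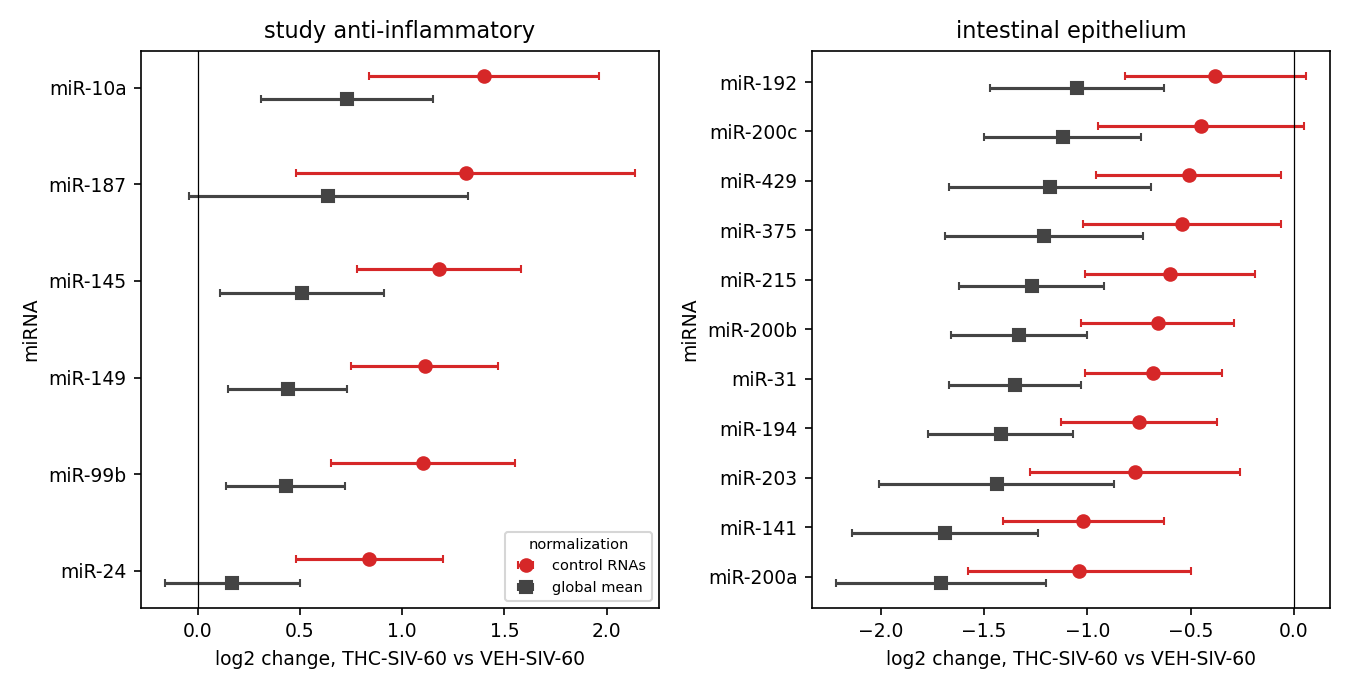
Log2 change of each member of the study's anti-inflammatory list (left) and of the epithelial list (right) in THC-SIV-60 against VEH-SIV-60, 4 samples each, with bars for standard errors, circles relative to the control RNAs and squares under global mean normalization. The study's members move from between 0.84 and 1.40 to between 0.17 and 0.73, and the epithelial members stay below 0 on either scale.

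THC-SIV was compared with THC-only to ask what infection does under THC at matched days. On day 60 miR-134, of the imprinted cluster, rose in the infected animals by 2.55 ± 0.62 (4 against 3 samples, adjusted p = 0.0267, 1.77 under global mean), as did miR-214 by 1.99 ± 0.52 (adjusted p = 0.0267, 1.21 under global mean), miR-125a-5p by 2.15 ± 0.50 (adjusted p = 0.0267, 1.37 under global mean) and miR-10b by 2.34 ± 0.66 (adjusted p = 0.0279, 1.57 under global mean). miR-802 and miR-1208 fell (−1.58 ± 0.51, adjusted p = 0.0411; −4.72 ± 1.44, adjusted p = 0.0382). Of the study's list 4 members rose (5 over the list alone), miR-99b by 1.76 ± 0.49, miR-149 by 1.39 ± 0.39 and miR-24 by 1.37 ± 0.39 (adjusted p = 0.0279 each) and miR-145 by 1.36 ± 0.43 (adjusted p = 0.0388). Under global mean 0 did (1 over the list alone). Epithelial members were again lower, with 4 past the threshold under global mean (11 over the list alone), among them miR-194 at −1.54 ± 0.38 (adjusted p = 0.0231) and miR-215 at −1.40 ± 0.37 (adjusted p = 0.0361). Mean control Ct minus mean miRNA Ct differed as well, by 0.78 (exact permutation p = 0.0571, adjusted p = 0.257), and mean miRNA Ct by −0.85 (exact permutation p = 0.0286, adjusted p = 0.257). As lists relative to all assays, epithelium stood at −1.23 and the study's list at 0.78 (exact permutation p = 0.0857 and adjusted p = 0.223 each). The epithelial value was −2.09 in cohort 1 (2 against 2 samples) and −0.33 in cohort 2 (2 samples against HM74 alone), and −0.71 without GP68 (exact permutation p = 0.1). Fibroblasts stood at 0.70 (exact permutation p = 0.0571, adjusted p = 0.223) and myeloid cells at 0.89 (exact permutation p = 0.0286, adjusted p = 0.186) in 4 of 4 samples.

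Day 60 gave 40 assays, 38 higher and 2 lower, and 16 under global mean, 5 higher and 11 lower. The paired fit gave 0, so none of the miRNAs named here passed in it. Leaving out THC-only-60 GH61, HM74 or HE44 gave 0, 0 and 7, and leaving out THC-SIV-60 FT59, GP68 or HN56 gave 0, 0 and 76. On days 14 and 30 limma gave 0 assays, with 23 and 21 at an unadjusted p under 0.05. miR-190b stood at 2.45 ± 0.92 on day 14 and 2.85 ± 0.98 on day 30 (adjusted p = 0.453 and 0.479), higher in 4 of 4 and 3 of 3 samples, and at 2.26 ± 0.92 on day 60 (adjusted p = 0.104), higher in 4 of 4. miR-575 stood at 8.68 ± 2.05 on day 14 (adjusted p = 0.0869, and 0.048 under global mean). Leaving out THC-only-14 HE44 or THC-SIV-14 FT59 gave 3 and 1 on day 14, and leaving out THC-only-30 HM74 or HE44 gave 3 and 2 on day 30.

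**Figure D4:**
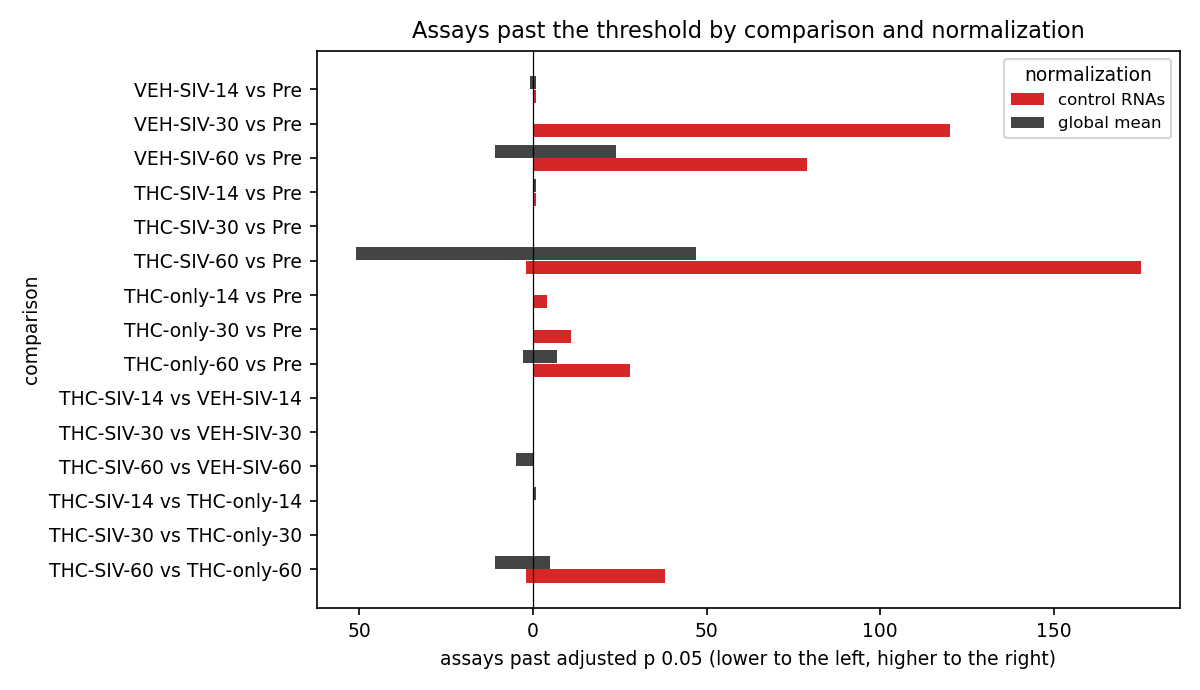
Number of assays with an adjusted p under 0.05 in limma for the 15 comparisons, with higher assays to the right and lower to the left, relative to the control RNAs (red) and under global mean normalization (dark). The 120 higher assays of VEH-SIV-30 against Pre become 0, and the 175 higher and 2 lower assays of THC-SIV-60 against Pre become 47 and 51.

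The day 60 samples were then set against days 14 and 30 within animals, a comparison added after the values above were seen. Smooth muscle miRNAs were higher on day 60 in 11 of 11 animals, by 1.82 ± 0.62 log2 relative to all assays (SD, exact sign-flip permutation p = 0.000977, the smallest possible, adjusted p = 0.00423). They were higher by 1.48 ± 0.79 in THC-only, 1.89 ± 0.64 in VEH-SIV and 2.01 ± 0.52 in THC-SIV, and miR-143 changed by 1.90, 2.29 and 2.18 in these arms. The study's list rose in 11 of 11 animals as well, by 0.72 ± 0.33 (exact permutation p = 0.000977, adjusted p = 0.00423). It rose by 0.44 in THC-only, 0.63 in VEH-SIV and 1.03 in THC-SIV. The study's list shares miR-145, 1 of its 6 members, with the smooth muscle list. It was not recomputed without miR-145, so how far the rises are separate was left open. miR-145 changed by 1.43, 2.23 and 2.33 in these arms. If the THC-only-14 labels of HM74 and HE44 are exchanged, HE44 goes to −0.23 for the study's list and −0.01 for the lentivirus list. Its smooth muscle value stays at 0.36. Lentivirus-targeting miRNAs rose by 0.52 in 11 of 11 animals, fibroblast miRNAs by 0.57 and endothelial miRNAs by 0.85 in 10 of 11 each. The let-7 list rose by 0.39 (adjusted p = 0.0106) and the neuronal list by 0.30 (adjusted p = 0.0282), while the miR-17 family fell by 0.37 (adjusted p = 0.0163) and the list responsive to inflammation by 0.32 (adjusted p = 0.0292), so that 10 of 13 lists differed. Epithelial miRNAs fell, by 0.68 ± 0.88 on average (exact permutation p = 0.0107, adjusted p = 0.0174), with −0.25 ± 0.23 in THC-only, −0.16 ± 0.43 in VEH-SIV and −1.52 ± 0.95 in THC-SIV. In THC-SIV each of the 11 epithelial members was lower in 4 of 4 animals, from −1.01 for miR-141 to −1.86 for miR-215. The difference between THC-SIV and VEH-SIV in this epithelial change was −1.36 (exact permutation p = 0.0571, adjusted p = 0.247). A limma test of the arm by day difference called 0 assays for THC-SIV against VEH-SIV, day 60 against day 30. There 94 had an unadjusted p under 0.05, with a smallest adjusted p of 0.0915. Under global mean these were 39 and 0.3. For day 60 against day 14 on the control scale they were 33 and 0.507, with 0 called. VEH-SIV against THC-only gave 0 calls on the control scale as well. There 10 assays for day 60 against day 14 and 7 against day 30 had an unadjusted p under 0.05.

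**Figure D5:**
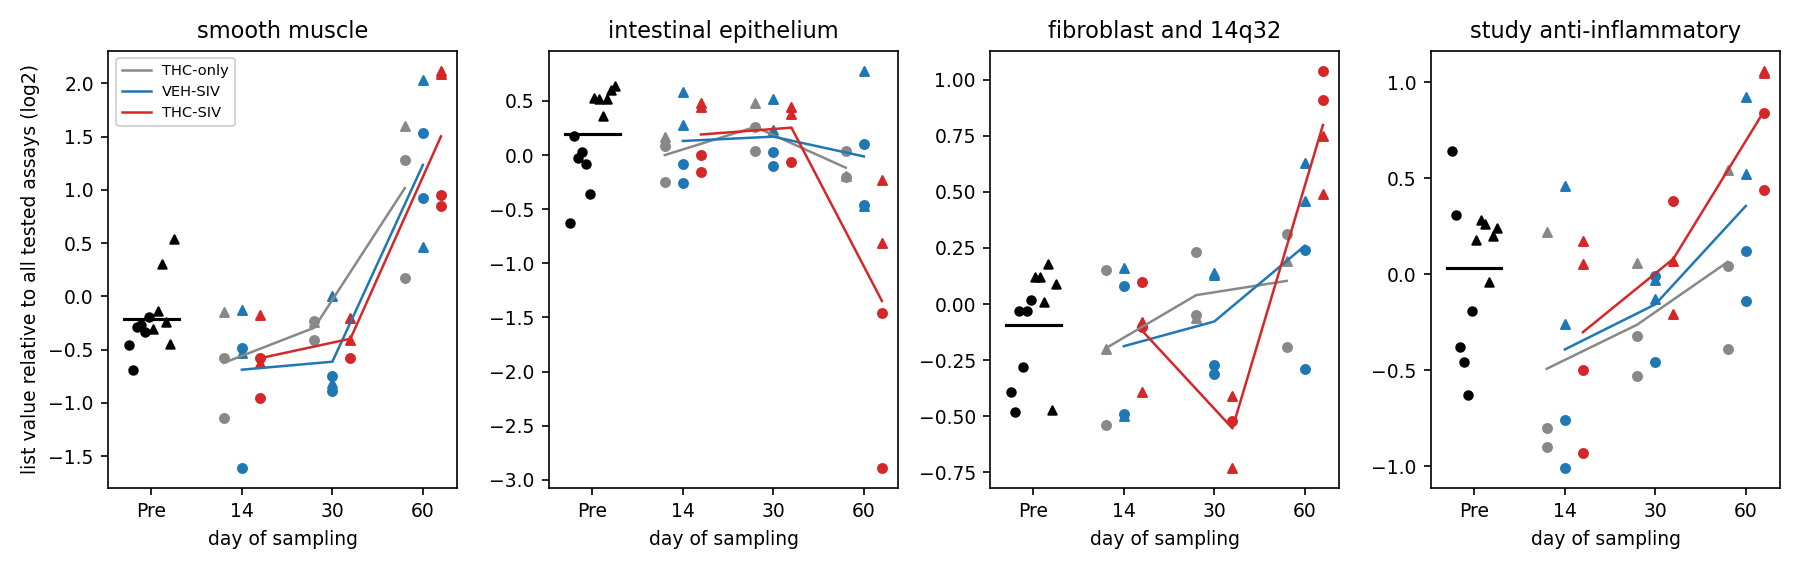
Value of 4 lists in each sample in log2 relative to all tested assays by day of sampling, with circles for cohort 1, triangles for cohort 2, lines joining arm means and a bar for the Pre mean. The smooth muscle list is higher on day 60 in all 3 arms, and the lowest epithelial values, −2.89 and −1.46, are those of GP68 and FT59 in THC-SIV-60.

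Some assays detected too rarely for the limma comparisons were detected more often after Pre. Fisher's exact test with adjustment called 7 to 44 assays per later group, each detected more often than in Pre, with 44 in THC-SIV-60. At an unadjusted p under 0.05 there were 43 to 65 per later group. THC-SIV-60 had 56 of these and did not stand out, while THC-only-30 had 65, of which 13 were called. Between later groups of the same day 0 assays passed, with 0 to 5 at an unadjusted p under 0.05, where the smallest exact p was 0.0286, or 0.1 for 3 against 3 samples. In the authors' deposited table, 59 of 419 p-values for THC-SIV-60 against Pre were under 0.05. For THC-SIV-60 against VEH-SIV-60 it held 20 of 402, about the share due by chance if these p-values are unadjusted. By the ratio on the same line all 20 were higher and 0 lower, so the share alone does not show that they are due to chance. The median of all tested assays was also higher there, by 0.70 log2.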

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

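The tests of infection, of a separate run, of the control RNAs, of a deeper sample and of the epithelial difference below were chosen after the results were seen (not planned), and those of RNA damage before. Detected assays and signal relative to the control RNAs were higher after Pre in all arms. Infection was excluded as the whole cause, because 9 of 9 later samples of uninfected animals had more detected assays than the highest Pre sample. A change of the control RNAs relative to all miRNAs was left open: under global mean normalization 54.8% of the calls against Pre were higher, but centring each sample on its own mean fixes that balance. A separate run of the Pre samples could not be told apart from time, since 0 of 32 later samples lay inside the Pre range of detected assays.

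Smooth muscle miRNAs such as miR-143 and miR-1 were higher on day 60 in all 3 arms. Infection was excluded as the whole cause, since the list changed by 1.48 ± 0.79 in the 3 uninfected animals. A deeper sample of the gut wall at necropsy could be the reason, as 15 of 15 changes of the 5 miRNAs in 3 arms exceeded 0.5 log2, but day 60 and necropsy coincide and the test cannot tell. Damage of RNA was not separable either: the smooth muscle change and control Ct minus mean Ct had r = −0.43 (permutation p = 0.198) and rho = −0.18 (permutation p = 0.595) in 11 animals, r = −0.20 without the 2 farthest, and an adjusted p of 0.396 over 2 correlations.

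Epithelial miRNAs such as miR-194 and miR-200b were lower in THC-SIV-60 than in VEH-SIV-60. THC may be the cause, but the difference of −1.33 had an exact permutation p of 0.0857. FT59 and GP68 carried much of it, with −0.51 left without these 2 animals. A smaller share of epithelium was not settled, with fibroblast minus leukocyte lists differing by 0.69 (exact permutation p = 0.2). Damage of RNA could not be told either: r = −0.11 (permutation p = 0.812) and rho = −0.32 (permutation p = 0.498) over the 7 day 60 samples of the other arms, without those of THC-SIV, r = 0.12 without the 2 farthest, adjusted p = 0.812 over 2 correlations.

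The smooth muscle list of HT49 in VEH-SIV-30 was 0 against −0.89 to −0.75 in the other 3 samples. The endothelial list of FE07 in VEH-SIV-30 was −1.88 against −0.34 to −0.17. In 85 sets of 4 values 2 such samples were found, where about 4 are due by chance. The epithelial list moved in opposite directions from day 14 to day 30 in every animal of THC-SIV (−0.06) and THC-only (0.26), a difference of −0.32 (exact permutation p = 0.1, the smallest possible for 3 against 3, adjusted p = 0.78). The plant miR159a of pool B was detected in 18 of 32 later samples, down to a Ct of 10.51, and in 2 of 12 Pre samples (Fisher's exact p = 0.0389), with 5 of 9 in uninfected and 13 of 23 in infected animals.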

How the results depend on the processing

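Counts of assays past the threshold and list results were recomputed under each alternative, and most moves followed the normalization and single samples. A Ct limit of 32 and the random replicate block moved no count by over 1.5 times. The fixed replicate block gave 151 for THC-SIV-60 against Pre, and apart from the counts given here it moved none by over 1.5 times. Of 250 values of named miRNAs it left 174 with the same call and weakened 63. Under global mean normalization the counts against Pre were 2 for VEH-SIV-14, 0 for VEH-SIV-30, 35 for VEH-SIV-60, 98 for THC-SIV-60, 0 for THC-only-14, 0 for THC-only-30 and 10 for THC-only-60. They were 5 for THC-SIV-60 vs VEH-SIV-60, 1 for THC-SIV-14 vs THC-only-14, 16 for THC-SIV-60 vs THC-only-60 and 9 of 195 for the gene lists, and relative to all assays 9 for the gene lists, against 35 on the control scale, all higher. With the authors' deposited normalized table the counts were 2 for VEH-SIV-14, 1 for VEH-SIV-30, 0 for THC-only-14, 6 for THC-only-30 and 19 for the gene lists. RNU44 and RNU48 without U6 gave 202 for VEH-SIV-30, 158 for VEH-SIV-60, 64 for THC-only-60, 21 for THC-SIV-60 vs THC-only-60 and 53 for the gene lists. U6 alone gave 2 for VEH-SIV-14, 3 for VEH-SIV-30, 8 for VEH-SIV-60, 98 for THC-SIV-60, 0 for THC-only-30 and 2 for THC-only-60. It gave 2 for THC-SIV-60 vs VEH-SIV-60, 1 for THC-SIV-14 vs THC-only-14, 21 for THC-SIV-60 vs THC-only-60 and 7 for the gene lists. The median of the controls gave 204 for VEH-SIV-30, 133 for VEH-SIV-60, 7 for THC-only-30, 63 for THC-only-60 and 0 for THC-SIV-60 vs THC-only-60.

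A Ct limit of 40 gave 0 for THC-SIV-14. Setting values not detected to 35 gave 3 for VEH-SIV-14, 2 for THC-SIV-14, 1 for THC-SIV-30, 12 for THC-only-14 and 23 for THC-only-30. Assays detected in all samples gave 0 for THC-SIV-14 and 0 for THC-only-14, and no filter over all samples gave 1 for THC-SIV-14 vs THC-only-14 and 22 for THC-SIV-60 vs THC-only-60. The paired fit with the animal as a fixed replicate block gave 47 for VEH-SIV-30, 51 for VEH-SIV-60, 0 for THC-SIV-14, 0 for THC-only-14, 0 for THC-only-30, 2 for THC-only-60 and 0 for THC-SIV-60 vs THC-only-60. It gave 0 for the gene lists, where 4 pairs cannot reach a p under 0.125. Fits of only the groups compared gave 79 for VEH-SIV-30, 4 for THC-SIV-30, 0 for THC-only-30, 44 for THC-only-60 and 0 for THC-SIV-60 vs THC-only-60. With the labels of HM74 and HE44 exchanged in THC-only-14, this replicate block gave 0 for VEH-SIV-14, 60 for VEH-SIV-30, 0 for THC-SIV-14, 0 for THC-only-14, 0 for THC-only-30, 2 for THC-only-60, 1 for THC-SIV-60 vs VEH-SIV-60 and 0 for THC-SIV-60 vs THC-only-60. The cohort as a factor gave 2 for THC-SIV-14 and 2 for THC-SIV-30. With these labels exchanged it gave 2 for THC-SIV-14, 2 for THC-SIV-30, 27 for THC-SIV-60 vs VEH-SIV-60 and 70 for THC-SIV-60 vs THC-only-60. The cohort together with global mean gave 3 for VEH-SIV-14, 0 for VEH-SIV-30, 44 for VEH-SIV-60, 112 for THC-SIV-60, 0 for THC-only-14 and 0 for THC-only-30. It gave 8 for THC-SIV-60 vs VEH-SIV-60 and 1 for THC-SIV-14 vs THC-only-14. Without the 5 samples apart the counts were 14 for VEH-SIV-14, 37 for VEH-SIV-30, 134 for VEH-SIV-60, 13 for THC-SIV-14, 6 for THC-SIV-30, 0 for THC-only-14. They were 54 for THC-only-30, 65 for THC-only-60, 25 for THC-SIV-60 vs VEH-SIV-60, 2 for THC-SIV-30 vs THC-only-30 and 75 for THC-SIV-60 vs THC-only-60. Without FT59 and GP68 they were 91 for THC-SIV-60, 1 for THC-SIV-60 vs VEH-SIV-60 and 1 for THC-SIV-60 vs THC-only-60.

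Leaving out 1 sample gave, from lowest to highest, 0 to 1 for VEH-SIV-14, 5 to 153 for VEH-SIV-30, 46 to 95 for VEH-SIV-60, 1 to 3 for THC-SIV-14, 0 to 1 for THC-SIV-30, 0 to 9 for THC-only-14, 6 to 12 for THC-only-30 and 8 to 31 for THC-only-60. It gave 0 to 45 for THC-SIV-60 vs VEH-SIV-60 and 0 to 76 for THC-SIV-60 vs THC-only-60. THC-SIV-14 vs THC-only-14 and THC-SIV-30 vs THC-only-30 gave 0 to 3 each. On the control scale the epithelial list in THC-SIV-60 against Pre ran from −0.35 to 0.31. Relative to all assays it stayed lower when each THC-SIV-60 sample was left out, from −1.91 without HN56 to −1.02 without GP68.

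Results that turned sign were mostly calls against Pre smaller than the median of all assays. Under global mean normalization they were miR-149 (−0.21) and miR-24 (−0.07) in VEH-SIV-30, and the lists of the study (−0.15), leukocytes (−0.31), neurons (−0.18), inflammation (−0.12), lentivirus (−0.24) and let-7 (−0.09) there. On that scale the epithelial list turned in VEH-SIV-60 (−0.24), the lists of leukocytes (−0.39), myeloid cells (−0.22), neurons (−0.15), inflammation (−0.84) and the miR-17 family (−0.58) in THC-SIV-60, and that of lentivirus in THC-only-60 (−0.01). The authors' deposited normalized table turned leukocytes in VEH-SIV-30 (−0.07), and U6 alone turned epithelium (−0.35) and the miR-17 family (−0.04) in VEH-SIV-60. Relative to all assays the lists that turned in VEH-SIV-30 were the study's (−0.19), epithelium (−0.02), leukocytes (−0.36), neurons (−0.22), inflammation (−0.17), lentivirus (−0.29) and let-7 (−0.13). On this scale epithelium turned in VEH-SIV-60 (−0.20), let-7 in THC-SIV-14 (−0.32), leukocytes (−0.35), myeloid cells (−0.18), neurons (−0.11), inflammation (−0.80) and the miR-17 family (−0.54) in THC-SIV-60, and lentivirus in THC-only-60 (−0.07). On the control scale erythrocytes turned in THC-SIV-60 without FT59 and GP68 (−0.32). The cause of these moves was not tested.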

Other observations

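The comparison of infected with uninfected animals, the samples apart and the exchanged labels in this part were chosen after values were seen (not planned), and the other splits were planned before. miR-190b was picked because it was high in the infected groups, so its own p on these samples tests nothing new. Each animal's change from Pre to the mean of its later samples was 2.75 ± 1.54 log2 (SD, lowest 0.43) in 8 infected animals and −0.04 ± 1.18 (highest 1.31) in 3 uninfected ones, with overlap. The adjusted p was 0.987 over 278 assays, and 0.99 under global mean, so a difference by infection was left open. With the THC-only-14 labels exchanged, miR-190b changed by 0.47 in HE44 and −0.05 in HM74, so the overlap with the lowest infected animal (0.43) was slight. In all 278 assays, 1 separated the infected from the uninfected animals without overlap (miR-203, 0.71 against 0.19), and 3 did under global mean, where 3 are due by chance (1.21% of assays). The smallest exact p for 8 against 3 animals was 0.00606.

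Of the assays too rarely detected for limma, 9 were detected in 4 of 4 VEH-SIV-14 samples and 0 of 12 Pre samples, among them miR-449, miR-504 and miR-887 (Fisher's exact p = 0.000549, adjusted p = 0.0171). This is not particular to infection: the uninfected THC-only groups had 14, 13 and 14 assays past the threshold on days 14, 30 and 60. miR-504 was also detected in 3 of 3 THC-only-60 samples (Fisher's exact p = 0.0022, adjusted p = 0.0394). 5 samples stood apart on the first principal component (17.4% of the variance): Pre FE07, Pre FT59, VEH-SIV-30 FE07 and THC-SIV-30 GP68 of cohort 1, and THC-only-14 HM74, of cohort 2 by its label. In the 4 of cohort 1, 33 of 251 assays did not overlap with the other 19 samples of that cohort, with miR-411 at −6.93 and miR-30a-5p at −4.47. The samples were picked on these same assays, so some such assays are expected and no chance value applies. With the labels of HM74 and HE44 exchanged all 5 belong to cohort 1, and 30 assays did not overlap with the other 18 samples.

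Other splits of the samples were made to see whether chance can be excluded. Against Pre the count was 120 for VEH-SIV-30 (highest other split 97, as large in 1 of 100 splits), 79 for VEH-SIV-60 (highest other 73, 1 of 100), 177 for THC-SIV-60 (highest other 83, 1 of 100), 11 for THC-only-30 (highest other 16, 3 of 100) and 28 for THC-only-60 (highest other 14, 1 of 100). Those splits mix animals, whereas later and Pre samples are of the same animals. Splits that part as many pairs number 16 for 4 animals and 8 for 3, too few for a share under 0.05, and their highest other count was 2, 73, 129, 3 and 3. The paired fit gave 47, 51, 151, 0 and 2 for these comparisons. Chance was not excluded by the splits for VEH-SIV-14 (1, highest other 17, 5 of 100), THC-SIV-14 (1, highest other 3, 6 of 100) and THC-only-14 (4, highest other 14, 7 of 100). For THC-SIV-30 the count was 0 (highest other 21), so every split is as large and the splits test nothing.

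Between later groups, a real count of 0 makes every split as large, so the splits cannot test chance there. THC-SIV against VEH-SIV gave 0 on day 14 (highest other split 4), 0 on day 30 (highest other 2), 0 on day 60 (highest other 18) and 0 for the mean of time points (highest other 30). The split by cohort gave 4, 2, 7 and 30 assays in these. It was the highest split on days 14 and 30 and for the mean of time points, which points to structure by cohort there, but on day 60 the split with 18 was another. With the cohort as a factor the real splits gave 0 each, or 27 on day 60 with the labels of HM74 and HE44 exchanged in THC-only-14. THC-SIV against THC-only gave 0 on day 14 (highest other 3) and 40 on day 60. For the 40 chance was not excluded, with 2 of 35 splits as large and a highest other of 66. For day 30 the 10 splits are too few (0, highest other 2).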
